A study of Rattus norvegicus with 24 samples.

How the data were processed

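Per the labels' protocols, 6 punches of 1 mm were taken from the dorsal hippocampus of each sample. RNA was isolated with a column kit, messenger RNA was purified on oligo-dT beads, directional libraries were made and single-end reads were sequenced on an Illumina instrument. Mothers received the OPFR mixture or 20 ul of ethanol on a treat. The age label and the design text give postnatal day 10, while the extraction protocol speaks of adult offspring, and postnatal day 10 is used here. The labels do not state that the 6 libraries of a group came from separate animals, so p-values measure the spread between these libraries. Titles carry a number that a male and a female of the same exposure group can share. The labels do not say what that number marks, and offspring of 1 mother, if present, would not be independent.

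The authors deposited 1 table of raw counts, with whole numbers for 30452 Ensembl rat gene identifiers in 24 libraries and no normalization. FastQC, STAR, HTSeq and DESeq2 are named as tools per the submitters' processing notes, without versions, roles or order. The genome build, annotation release and strand setting of the counting were not given in the sources used here. Overlapping genes, antisense genes and near-identical copies can therefore share or split counts. For the same reason a count near 0 can hold stray reads. Every column matched 1 sample title. No pair of libraries within a group agreed within counting noise: the smallest chi-square per degree of freedom over genes with at least 240 counts in all libraries together was 22.6, so all 24 libraries were kept as separate samples.

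The reference table lists 47357 rat genes without Ensembl identifiers, and 0 identifiers could be matched to a symbol. The 37 gene lists fixed before the data were examined were therefore not tested, gene names and positions are not given, and checks that need gene length or base composition were not made. The rule for genes named in the text, fixed beforehand, took genes with an adjusted p under 0.05, a mean of at least 1 CPM and a symbol: the 10 largest rises, the 10 largest falls and the 10 smallest p-values per comparison, or the 5 smallest p-values where fewer than 5 genes passed. Without symbols no gene met it. Up to 2 identifiers per direction were named instead by smallest p or by largest difference, after their values were seen.

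Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 17047 genes. The 13405 genes removed held 0.0128% of all counts, and 7164 genes were at 0 in every library. Library sizes were scaled by TMM factors. One quasi-likelihood model with 4 group means was fitted to all 24 libraries, with no covariate. From it came 6 two-sided comparisons: OPFR against control in males, in females and averaged over the sexes, the difference between the male and female effects, and males against females in controls and in OPFR offspring. p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. CPM values use TMM-scaled library sizes, and log2 CPM for the components used a prior count of 2. Confidence intervals of 95% come from the quasi-likelihood standard errors. Component scores were tested with 100000 permutations. Depth per library was 59847225 to 77889710 counts, and libraries of 1 group differed from each other by more than counting error, so the standard errors mainly measure the spread between libraries.

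The edgeR step was tested on simulated counts for 17047 genes with 200 genes changed, 50 at each of 4 sizes, drawn with the observed means and dispersions but with genes independent of each other. For the comparison in males, 26% of genes changed 1.25-fold, 46% of those changed 1.5-fold, 86% of those changed 2-fold and 92% of those changed 4-fold were recovered, with 0 false calls among 125. For the averaged comparison the recovered shares were 34%, 64%, 84% and 100%, with 13 false calls among 154. Correlation between genes, which the real libraries show, was not simulated.

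Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, no filter on low counts, a stricter filter (at least 1 CPM in 6 libraries), DESeq2 1.42.0, limma 3.58.1 with voom, fits of the compared groups alone, 1 surrogate variable from sva 3.50.0, each library left out in turn, an adjusted p threshold of 0.1, the title number as a block and counts summed per title number. A covariate from a set of covarying genes and DESeq2 without OPFR male 2 were added after the data were seen. Figures were drawn with matplotlib.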

Results

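Messenger RNA was sequenced from tissue punches of the dorsal hippocampus, a brain region needed for memory of places and events, in Wistar rat offspring whose mothers had eaten a treat carrying either ethanol vehicle or a mixture of organophosphate ester flame retardants (OPFR), chemicals added to furniture foam and plastics. The labels give a maternal dose of 1000 ug of the mixture, or 3.3 mg per kg of body weight, each day from conception to postnatal day 10. The 24 libraries fell into 4 groups of 6: control males, control females, OPFR males and OPFR females. By the running number at the end of the titles, every control library came before every OPFR library. The title numbers that a male and a female can share were also all lower in controls. An effect of either order cannot be told apart from exposure, which it could mimic or hide. Total counts per library ran from 59847225 to 77889710, with a median of 70306632, and 19137 to 19640 genes had at least 1 count in a library. Group means were 70272574 ± 2873424 (SD, n = 6) in control males, 68347178 ± 5515305 (SD, n = 6) in control females, 69852494 ± 4560315 (SD, n = 6) in OPFR males and 70380571 ± 5582094 (SD, n = 6) in OPFR females. Genes are given by Ensembl rat identifier, since the deposited counts and the reference used here do not pair these identifiers with gene symbols. Known functions and chromosomal positions are therefore left out, and groups of genes are described by their expression alone.

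Apart from the genes that differed between the sexes, no separation of the libraries by exposure was detected on the leading components of the transcriptome. The principal component analysis used 17036 genes, all those tested except the 11 called between the sexes, and so it does not test sex. The first component held 20.3% of the variance and the second 12.5%. Scores of the 12 OPFR and 12 control libraries on the first component were not separated by a two-sided permutation test (p = 0.749). Of the first 5 components, the third, with 8.6% of the variance, had the smallest p for exposure (two-sided permutation test, p = 0.0339), which was 0.169 after Benjamini-Hochberg adjustment over the 5 components.

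**Figure D1:**
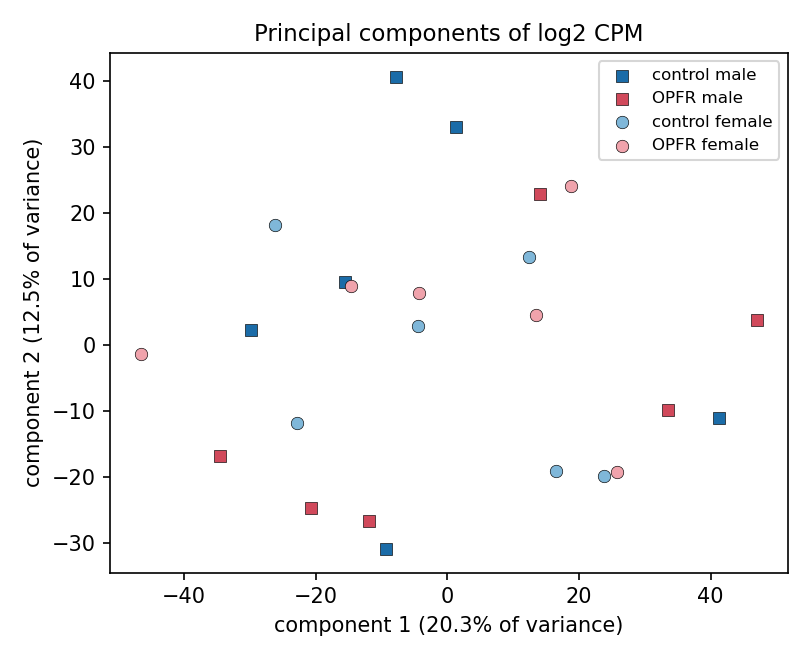
Scores of the 24 libraries on the first component (x axis, 20.3% of the variance) and the second (y axis, 12.5%) of log2 CPM over 17036 genes. Each point is 1 library, squares are males and circles females, and the 4 groups lie intermixed.

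The first comparison asked which hippocampal genes differed between male offspring of OPFR-exposed and vehicle-exposed mothers. No gene passed the test among the 17047 tested (edgeR quasi-likelihood test, smallest Benjamini-Hochberg adjusted p = 0.887). At an unadjusted p under 0.05 there were 693 genes, 332 higher and 361 lower in OPFR males, against 852 that chance alone would give on average. This number depended on single libraries: it was 403 without control male 1, 411 without control male 3 and 431 without OPFR male 6, but 1087 without OPFR male 5, 1375 without control male 5 and 1626 without control male 6. It was 456 in a fit of the males alone. With no filter on low counts it was 1098, but that fit tested more genes, so the 852 of chance does not apply to it. Among genes with a mean of at least 1 CPM, a count scaled to library size, the smallest p belonged to ENSRNOG00000054508, which measured 4.22 ± 4.08 CPM (SD, n = 6) in OPFR males and 0.803 ± 0.539 CPM (SD, n = 6) in control males. Its log2 difference was 2.39 with a standard error of 0.53, and the edgeR adjusted p was 0.887. OPFR male 2 alone held 11.8 CPM of this gene, while the other OPFR males ranged from 0.689 to 4.73 CPM. DESeq2 called this 1 gene (adjusted p = 0.0162), but called 0 genes with OPFR male 2 left out, when its log2 difference went from 2.39 to 1.74 with a standard error of 0.46. limma voom called 0. For 85.9% of the 14147 genes with at least 1 CPM, the 95% confidence interval of the fold difference lay within 1.5-fold in either direction, and for 95.8% it lay within 2-fold.

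In female offspring the same question gave the same count. No gene passed the edgeR test (smallest adjusted p = 0.946), and neither DESeq2 nor limma voom called any, with 0 genes each. The unadjusted p was under 0.05 for 764 genes, 444 of them higher and 320 lower in OPFR females. It was under 0.05 for 490 genes without OPFR female 4, 493 without OPFR female 5 and 505 without control female 1. Without control female 5 it was under 0.05 for 1455 genes, and without OPFR female 2 for 1515. With no filter on low counts, in a fit that tested more genes, it was under 0.05 for 1161. ENSRNOG00000025587 had the smallest p among genes with at least 1 CPM. It measured 2.04 ± 0.623 CPM (SD, n = 6) in OPFR females and 4.45 ± 0.57 CPM (SD, n = 6) in control females, a log2 difference of -1.13 with a standard error of 0.27 (edgeR adjusted p = 0.946). In males the same gene stood at 2.60 ± 1.12 CPM (SD, n = 6) with OPFR and 3.30 ± 1.08 CPM (SD, n = 6) in controls. The 95% interval lay within 1.5-fold for 86.1% of the 14147 genes and within 2-fold for 96.8%.

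Averaging the male and female effects gave the smallest standard errors for exposure, with a median of 0.077 on the log2 scale against 0.11 within either sex. These errors count libraries of 1 title number as separate samples. The estimated correlation within a number was 0.292, so the errors and the intervals built on them are likely too small. No gene passed the edgeR test for the averaged effect (smallest adjusted p = 0.636), and limma voom called 0. There were 1312 genes at an unadjusted p under 0.05, of which 663 were higher and 649 lower with OPFR, against 852 by chance. With counts summed over the libraries of 1 title number there were 766. ENSRNOG00000012295 had the smallest p among genes with at least 1 CPM. Its level was 31.4 ± 1.82 CPM (SD, n = 6) in OPFR males and 35.2 ± 1.39 CPM (SD, n = 6) in control males, and 31.0 ± 0.609 CPM (SD, n = 6) in OPFR females against 34.5 ± 2.44 CPM (SD, n = 6) in control females. The averaged log2 difference was -0.16 with a standard error of 0.035 (edgeR adjusted p = 0.636). DESeq2 called 2 genes, ENSRNOG00000012295 and ENSRNOG00000054508, each at an adjusted p of 0.0446, and 0 genes with OPFR male 2 left out. Without that library the DESeq2 log2 difference of ENSRNOG00000012295 was about as large, -0.15 with a standard error of 0.034 (DESeq2 adjusted p = 0.113). The DESeq2 averaged difference of ENSRNOG00000054508 went from 2.98-fold (SE 0.345 on the log2 scale) to 2.38-fold (SE 0.315, DESeq2 adjusted p = 0.206), so most of it stayed without that library. The 95% interval of the averaged effect lay within 1.5-fold for 93.8% of the 14147 genes. For those genes a larger mean difference was outside the interval, which is likely too narrow because of the shared title numbers.

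**Figure D2:**
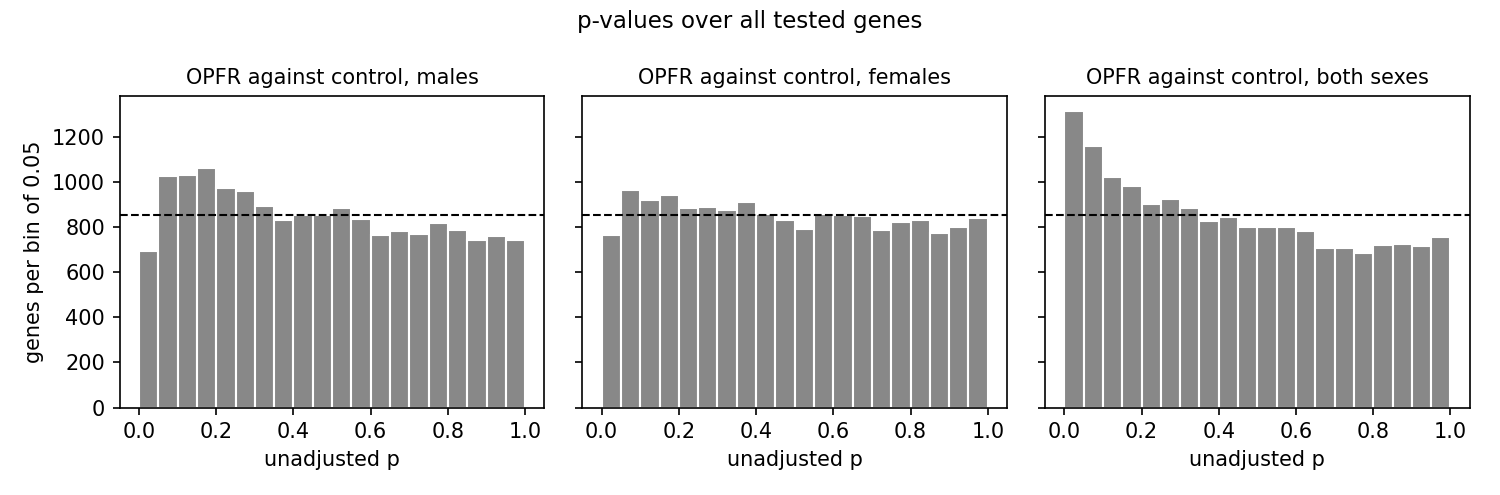
Number of genes (y axis) in each bin of unadjusted p (x axis, bins of 0.05) from the edgeR quasi-likelihood tests of OPFR against control in males, in females and averaged over the sexes, each over 17047 genes. The dashed line is the 852 genes per bin that chance alone would give, and the lowest bins hold 693, 764 and 1312 genes.

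Whether exposure acted differently in the sexes was tested as the difference between the male and female OPFR effects. No gene passed (edgeR, smallest adjusted p = 0.999), DESeq2 and limma voom each called 0 genes, and 346 genes had an unadjusted p under 0.05. That number fell to 243 without control male 4 and 249 without OPFR female 4. It rose to 523 without OPFR male 5, 587 without control male 5 and 736 without control female 5. It was 785 without control male 6 and 867 without OPFR female 2. With the title number as a block, on the 18 libraries in same-number pairs, it was 2030, with 0 genes called. That is above the 852 that chance alone would give on average. The number was 798 with no filter on low counts, in a fit that tested more genes. It was 541 with a covariate, chosen after the data were seen, from a set of covarying genes. This contrast counts libraries of 1 title number as separate samples and sets males against females. Given the estimated correlation of 0.292 within a number, its errors are likely too large. It had the widest error, with a median standard error of 0.15 on the log2 scale and a 95% interval within 1.5-fold for 74.8% of the 14147 genes. Across these genes, which are not independent replicates, the male and female log2 differences had a Pearson correlation of 0.138 and a Spearman correlation of 0.192, with a covariance of 0.00358. Since no gene was called in either sex, no called genes were shared. At an unadjusted p under 0.01 there were 75 genes in males and 105 in females, and 1 was common to both with the same sign, where independent lists would share 0.232.

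Sex itself was visible in a small set of genes. In control offspring 10 genes differed between males and females (edgeR quasi-likelihood test, adjusted p under 0.05), 4 higher in males and 6 higher in females. In OPFR offspring 11 genes differed, 4 higher in males and 7 higher in females. All 10 genes called in controls were also called in OPFR offspring with the same sign, where independent lists of these sizes would share 0.00645. The remaining gene, ENSRNOG00000057706, had an adjusted p of 0.0676 in controls, and its sex difference was not shown to depend on exposure (adjusted p = 0.999 for the interaction). At an unadjusted p under 0.05 there were 284 genes in controls and 531 in OPFR offspring. In controls the number was 495 without control male 6, 508 without control male 3 and 617 without control female 5. In OPFR offspring it was 333 without OPFR male 6, 799 without OPFR male 3 and 906 without OPFR female 2. With no filter on low counts, in a fit that tested more genes, the numbers were 635 in controls and 931 in OPFR offspring. With the title number as a block they were 1388 and 1697. The main errors count libraries of 1 title number as separate samples. Given the estimated correlation of 0.292 within a number, they are likely too large for a comparison of males with females.

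The 4 genes higher in males were close to absent from females. ENSRNOG00000057231 measured 34.1 ± 2.97 CPM (SD, n = 6) in control males and 0.123 ± 0.106 CPM (SD, n = 6) in control females. With OPFR it measured 34.1 ± 3.96 CPM (SD, n = 6) in males and 0.0313 ± 0.0266 CPM (SD, n = 6) in females. ENSRNOG00000060048 measured 86.2 ± 6.72 CPM (SD, n = 6) in control males and 0.30 ± 0.196 CPM (SD, n = 6) in control females. In OPFR offspring it stood at 90.7 ± 3.40 CPM (SD, n = 6) in males and 0.109 ± 0.112 CPM (SD, n = 6) in females. Summed over the 4 genes, every one of the 12 males had at least 10096 counts and no female had more than 80, so that the libraries formed 2 classes that followed the titles without exception. These genes were picked by the sex in the titles and could not be matched to a known sex chromosome gene, so they do not independently check which class is male.

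Of the genes higher in females, 6 were expressed in both sexes and differed by less than 2-fold, from 1.18 to 1.63-fold in controls and from 1.23 to 1.61-fold in OPFR offspring. ENSRNOG00000060793 measured 219 ± 10.96 CPM (SD, n = 6) in control females and 141 ± 5.24 CPM (SD, n = 6) in control males, a male minus female log2 difference of -0.64 with a standard error of 0.041 (edgeR adjusted p = 2.44e-10). With OPFR the levels were 230 ± 6.58 CPM (SD, n = 6) in females and 145 ± 8.11 CPM (SD, n = 6) in males, a log2 difference of -0.67 with a standard error of 0.041 (edgeR adjusted p = 9.92e-11). The seventh, ENSRNOG00000065796, was nearly confined to females. It measured 7.20 ± 2.57 CPM (SD, n = 6) in control females and 0.161 ± 0.329 CPM (SD, n = 6) in control males (edgeR adjusted p = 8.12e-05). Of the 69 counts in control males, 59 lay in control male 1. In OPFR females it measured 7.52 ± 3.25 CPM (SD, n = 6), and the 6 OPFR males held 3 counts in all (edgeR adjusted p = 1.91e-06).

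**Figure D3:**
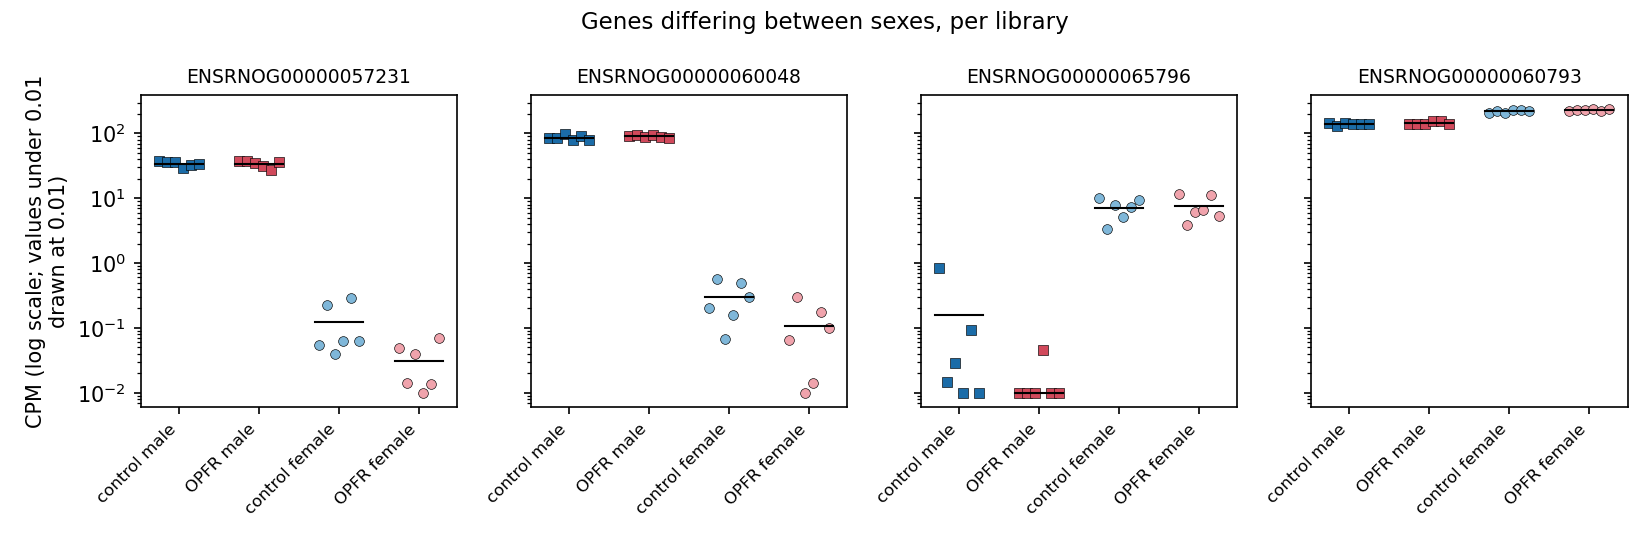
CPM per library (y axis, log scale, values under 0.01 drawn at 0.01) of 4 genes that differed between the sexes, in the 4 groups of 6 libraries (x axis), with a bar at each group's mean. ENSRNOG00000057231 and ENSRNOG00000060048 lie far higher in males, ENSRNOG00000065796 far higher in females, and ENSRNOG00000060793 moderately higher in females, in both exposure groups.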

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

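The splits within sex and within exposure group and the tests for a library standing apart were planned. The genes and the gene set that the latter tests used were chosen after values were seen. The splits by title number were chosen after the results were seen. What each split test would show was written down only after its result was seen. Neither sex comparison is explained by an arbitrary grouping of the libraries. Of 100 splits of the libraries within each exposure group, the real split included, 1 gave as many as the 10 genes called between the sexes in controls, and the highest of the others gave 2. For OPFR offspring 1 of 100 gave 11 genes, and the highest of the others gave 1. For exposure, where the real split called 0 genes, all 100 splits within sex necessarily gave as many in each of the 4 comparisons, so this count decides nothing about chance. Of the other 99 splits, 6 called any gene in males, 5 in females, 1 for the averaged effect and 5 for the difference between the sexes, and the median was 0 in each. The highest called 1500 genes in males, 63 in females, 1 for the averaged effect and 40 for the difference between the sexes. A split that calls so many more genes than the real one may point to some structure of the male libraries. This rests on 1 split, and what it follows was not tested. Of the other 99 splits that kept title numbers together, 0 called any gene in males. Each number occurs once within a sex, so this does not test whether the number underlies such a structure.

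The averaged exposure comparison held 1312 genes at an unadjusted p under 0.05, more than the 852 of chance. In splits that gave libraries of 1 title number to the same side, 36 of 100, the real one included, reached at least 1312, and the highest of the others reached 2930. Splits within sex that ignored the title number reached it too, in 18 of 100, with a highest of 3274. The excess is therefore within what arbitrary splits of these libraries give, and neither exposure nor the title number is shown to be its source. It was not seen with the number as a block (854 genes) or with counts summed per number (766). For the averaged effect, splits that kept title numbers together called up to 182 genes and splits within sex up to 1. The real correlation of male with female log2 differences, 0.138 with a covariance of 0.00358, was reached in 61 of 100 splits that kept title numbers together (median covariance 0.00432) and in 35 of 100 splits within sex (median covariance 0.00085).

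Over 40 tests of a group of 6 for a library standing apart, 5 were positive. Chance would give about 2 for normally spread values picked without regard to the data. That number does not hold here, since genes were picked by their values and ENSRNOG00000065796 lay near 0 in males. OPFR female 1 had 59847225 counts, against 70038824 to 76067867 in the other OPFR females. ENSRNOG00000065796, the gene nearly confined to females, measured 0.828 CPM in control male 1 and at most 0.0928 CPM in the other control males. The same gene measured 0.0452 CPM in OPFR male 4, from 3 counts, and 0 in the other OPFR males. ENSRNOG00000054508 measured 11.8 CPM in OPFR male 2 and 0.689 to 4.73 CPM in the other OPFR males. ENSRNOG00000012295 measured 38 CPM in control male 4 and 34.1 to 34.9 CPM in the other control males. Among the genes too low to be tested, ENSRNOG00000051360 had 224 counts in OPFR female 1 and at most 8 in any other library, and ENSRNOG00000058664 had 290 counts in OPFR male 5 and at most 2 elsewhere. Both are single libraries, and no explanation was tested for them.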

How the results depend on the processing

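The covariate from the covarying genes and DESeq2 without OPFR male 2 were chosen after the data were seen. With edgeR, OPFR calls stayed at 0 in males, in females, averaged and for the difference between the sexes under every scaling, filter, threshold, surrogate variable and added covariate, and with each library left out in turn (0 to 0 calls). limma voom also gave 0 for all 4. Genes at an unadjusted p under 0.05 ranged with each library left out from 403 to 1626 in males, 490 to 1515 in females, 946 to 1711 averaged and 243 to 867 for the difference between the sexes. Over the other alternatives they ranged from 456 to 1098, 669 to 1161, 766 to 1759 and 257 to 2030. The fits with no filter or with the stricter filter tested other numbers of genes, so the 852 of chance does not apply to them. DESeq2 called 1 gene in males and 2 averaged. With OPFR male 2 left out it called 0 in both, and the log2 difference of ENSRNOG00000054508 in males went from 2.39 (SE 0.487) to 1.74 (SE 0.455), and that of ENSRNOG00000012295 averaged went from -0.16 (SE 0.0352) to -0.15 (SE 0.0335). The averaged difference of ENSRNOG00000054508 went from 2.98-fold to 2.38-fold. As most of both averaged differences stayed, losing these calls does not show that they rested on that library. Why DESeq2 and edgeR differed was not tested. At an unadjusted p of 0.01 the males and females shared 1 gene. Sex calls numbered 9 to 11 in controls and 11 to 12 in OPFR offspring apart from the block, and with each library left out 9 to 11 and 11 to 11. Over 385 refits of 11 of the gene results named in the text, 382 kept direction and side of the threshold and 0 reversed. Of the rest, 2 became significant (both DESeq2) and 1 lost significance (ENSRNOG00000065796 between control sexes under the block). The averaged result of ENSRNOG00000054508, outside these 11, also became significant with DESeq2 (DESeq2 adjusted p = 0.0446, edgeR adjusted p = 0.636).

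The title numbers did not pair the libraries by the rule set beforehand: 5 of 9 same-number pairs had correlated deviations over 0.1 (range -0.0068 to 0.396), and 8 of 18 libraries correlated best with their own number. Same-number libraries were nevertheless alike beyond chance on average (mean correlation 0.197 against -0.0012 for random matches, permutation p = 0.00216). With the number as a replicate block, sex calls were 5 in controls, all 5 among the main 10, from fewer libraries, and 15 in OPFR offspring, 9 of them among the main 11. Genes at an unadjusted p under 0.05 between the sexes went from 284 to 1388 in controls and from 531 to 1697 in OPFR offspring. Both moved from below to above the 852 of chance. The block gave 0 calls for the averaged OPFR effect and for the difference between the sexes, where genes at an unadjusted p under 0.05 went from 346 to 2030. For the averaged effect they went from 1312 to 854, near the 852 of chance, with an estimated correlation of 0.292 within a number.

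The gene list tests, their alternatives and the alternatives for genes named by symbol were not run, because the identifiers had no symbols. Fits of the compared groups alone equal the main fit for the averaged effect and the difference between the sexes. Depth limits what can be said of genes with few counts, such as ENSRNOG00000065796 with 3 counts in all OPFR males.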

Other observations

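All tests in this part were chosen after the patterns were seen. Among 124 genes that varied strongly within groups, the largest cluster was a set of 73 genes whose levels varied together. Their mean log2 CPM ran from -0.859 to 4.61, a 44.4-fold range, and together they took from 0.0162% to 1.97% of a library's counts. ENSRNOG00000016275, the most abundant, ranged from 5.07 to 14620 CPM. The set's mean was 1.61 ± 1.11 (SD, n = 6) in control females, 1.84 ± 1.61 in control males, 1.88 ± 1.54 in OPFR females and 1.70 ± 2.44 in OPFR males. Its difference between OPFR and control was 0.066 (permutation test over 24 libraries, p = 0.923). The set's mean and the scores on the first component had a Pearson r of 0.906. The exposure tests of the set and of that component are therefore not separate results.

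Library depth does not account for this set: its score and total counts had a Pearson r of 0.026 (permutation p = 0.901) and a Spearman rho of 0.11 (p = 0.616) over 24 libraries, and r was 0.17 without the 2 libraries farthest from the median. Exposure alone does not account for it either, since the 12 control libraries alone spanned 16.7-fold. That span does not exclude a part for exposure. The lowest score was -0.859 in OPFR females and -0.672 in OPFR males, against 0.202 in control females and -0.088 in control males. The highest was 3.36, 4.61, 3.13 and 3.98 in these groups, in that order. Whether exposure widened the spread was not tested. A candidate explanation is that the punches took up different amounts of 1 neighbouring tissue. Each gene's CPM followed the sum of the others with a median Pearson r of 0.976, but the genes were picked for covarying, so that value cannot decide it, and without gene symbols no tissue can be named. With the set's mean as a covariate, OPFR calls stayed at 0 in all 4 comparisons.

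A second pattern was a group of 11 genes whose libraries fell on either side of a gap of 3.16 to 24.1-fold, as if the gene were on or off. Libraries sharing a title number were in the same state in 78 of 99 comparisons (78.8%), against 60.3% for other male and female libraries of the same exposure (permutation p = 0.00214). Neighbours in library order with different numbers agreed in 87 of 143 comparisons, fewer per pair (6.69 against 8.67 of 11 genes, two-sided permutation p = 0.0192). Several pairs share a library, so this p-value treats the pairs as more independent than they are. Some of the neighbours with different numbers were of the same sex, while every same-number pair was a male and a female. The libraries of every same-number pair were themselves neighbours in library order. Being neighbours alone thus did not go with as much agreement, but the number cannot be told apart from neighbours being handled together. For 9 of the 11 genes, control libraries lay on both sides of the gap, so exposure alone does not set their state. The other 2 genes were off only in 3 and 4 of the 12 OPFR libraries, their smallest adjusted p was 0.681, and whether exposure plays a part cannot be told apart from chance with so few off libraries. The labels do not say what the number marks, and why libraries of 1 number agree was not tested.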
